A study of Caenorhabditis elegans and Mus musculus with 30 samples.

How the data were processed

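RNA was sequenced from 18 worm libraries and 12 mouse libraries. The worms (Caenorhabditis elegans) were grown on bacteria carrying the empty vector or on bacteria for mrps-5 RNAi and, per the labels, harvested at the L4 stage after plating 5000 eggs at 20 °C. For each of the 2 foods, total, polysomal and monosomal RNA of whole worms was sequenced in 3 libraries, which makes 6 groups. The mice were germ-free and received doxycycline or amoxicillin at 50 mg per kg per day in the drinking water for 2 weeks. After 16 h of fasting the liver was taken, and total and polysomal RNA were sequenced in 3 libraries each, which makes 4 groups. Per the labels, ribosomal RNA was depleted before library preparation and polysomal fractions of more than 1 gradient run were pooled.

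For each organism the authors deposited log2 CPM values (reads relative to the effective library size) for each library, with 18442 worm genes and 18306 mouse genes. Per the labels, the authors used FastQC, Trimmomatic 0.32, HISAT2 2.0.4, HTSeq 0.6.1, edgeR and limma. The genome build and annotation release behind the tables, and the strand setting of the counting, are not given in the sources used here, so genes are identified by symbol and no coordinates are printed. The scale was checked on the values: with a prior count of 0.25 that grows with depth, every value returned a whole number of reads within a tolerance of 0.05 (largest deviation 0.01 in worm and 0.004 in mouse). The library sizes contained in the values matched TMM factors computed from the recovered reads in worm (ratio 1) and differed by a constant 0.999 in mouse. Among the mouse genes 1 has 0 reads in all 12 libraries, so the authors' filter or scaling may have drawn on further libraries that were not analysed here.

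Recovered depth ran from 14728300 to 25959514 reads in worm and from 11730903 to 18435822 reads in mouse. A gene with 3 reads has 0.095 to 0.28 CPM in worm and 0.163 to 0.261 CPM in mouse, and 3 reads per library is the floor used where all libraries of a group are at 0. Between replicate libraries the chi-square per degree of freedom over genes was 3.78 to 216, so replicates differ by more than counting noise and errors are taken between libraries. The median SD of log2 CPM within a group was 0.08 for empty vector total RNA, 0.14 for mrps-5 RNAi total RNA, 0.17 and 0.16 for the polysomal groups and 0.37 and 0.34 for the monosomal groups (5706 genes). In mouse it was 0.17 and 0.11 for total RNA and 0.2 and 0.18 for polysomal RNA (amoxicillin, then doxycycline; 6443 genes).

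Libraries were assigned to groups from their titles. The comparisons, the gene lists, the rule for naming genes and most of the other settings tried were fixed before the data were examined. The first choice had been a quasi-likelihood F-test for counts. Because the tables hold log2 values, limma took its place, as had been set for that case. Genes above 1 CPM in at least 3 libraries of the organism were tested, 14521 in worm and 14030 in mouse. One limma model with a mean per group was fitted to the deposited log2 values of all libraries of an organism, with the moderated test of limma and a mean-variance trend, and p-values were adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. The 12 comparisons were mrps-5 RNAi against empty vector in each of the 3 worm fractions, the change of the 3 differences between worm fractions with mrps-5 RNAi (interaction terms), polysomal against total and against monosomal RNA in empty vector worms, doxycycline against amoxicillin in both mouse fractions, the change of the polysomal to total difference with doxycycline, and polysomal against total RNA in amoxicillin mice. Because all groups share 1 estimate of the spread, the test is conservative for the even total RNA groups and too liberal for the uneven monosomal groups.

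Gene lists written for this purpose (24 for worm, 31 for mouse, each tested where at least 5 genes passed the filter) were tested with camera in limma at its preset correlation of 0.01 between genes and adjusted over the lists. The same test with a correlation estimated from the residuals of each list, and the rotation test fry, were alternatives. Genes of a list were also adjusted over that list alone. Overlaps expected of independent calls are the product of both counts divided by the genes tested.

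Named genes follow a rule. For each treatment comparison and interaction they are the 10 with the largest positive and the 10 with the largest negative log2 change among genes with an adjusted p below 0.05 and a mean of at least 5 CPM; for the treatment comparisons the groups must also not overlap. For the comparisons of fractions in control samples the number is 5 each way. From each list up to 2 called genes per direction with the lowest adjusted p are named, or, where none is called, the 2 most abundant. In every comparison mrps-5, atf-5 and atfs-1 (worm) or Atf4, Atf5 and Ddit3 (mouse) are looked at. Not every gene that the rule gives is printed. Genes named outside this rule are marked as chosen after their values were seen.

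The settings tried, chosen at that time, were median-ratio size factors in place of TMM, no filter, a filter of 5 CPM, limma-voom on the recovered reads, a fit to the libraries of the contrast alone, leaving out the genes that exceed 1 percent of the reads of a library (10 in worm and 10 in mouse) before scaling, a block on the replicate number, and leaving out each library in turn. The labels give no shared source for a replicate number, so pairing was checked on the correlation of deviations from the group mean. Only polysomal with monosomal RNA of empty vector worms (r = 0.31, 0.18 and 0.22) and total with polysomal RNA of amoxicillin livers (0.1, 0.26 and 0.32) had each r over 0.1, of 21 pairs of groups. Added after seeing the data were a prior count of 2, sample weights and a worm fit without the monosomal libraries. Every count of calls was also compared with other splits of the same libraries into groups of the same size, at most 100 per comparison. Fits were tested on data simulated after the real levels, spreads and depths, with only 200 genes changed.

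Recovered reads and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the tests with R 4.3.3, data.table (version 1.17.8) and limma 3.58.1. No library was left out. In mouse 45 genes share a symbol with another gene and were kept apart by their identifiers.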

Results

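Total, polysomal and monosomal RNA of worms fed empty vector bacteria or bacteria for mrps-5 RNAi, and total and polysomal RNA of livers from germ-free mice given doxycycline or amoxicillin, were compared gene by gene (3 libraries per group, 30 libraries of 11730903 to 25959514 reads). The series asks how a block of mitochondrial translation, by loss of a mitochondrial ribosomal protein or by an antibiotic that acts on bacterial-type ribosomes, is met by the cytosol. Log2 changes are given with their standard error and CPM values as mean ± SD of 3 libraries.

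The transcript of mrps-5, which encodes a protein of the small mitochondrial ribosomal subunit, was higher in the libraries labelled mrps-5 RNAi: 319 ± 211 CPM against 73.9 ± 3.85 CPM in total RNA (log2 change 1.90, SE 0.44, adjusted p = 0.03). The 3 labelled libraries held 154, 557 and 246 CPM and the 3 empty vector libraries 74.4, 69.8 and 77.5 CPM. In polysomal RNA the levels were 189 ± 68.9 and 150 ± 13.9 CPM (log2 change 0.27, adjusted p = 0.911), and in monosomal RNA 1410 ± 752 and 123 ± 29.3 CPM (log2 change 3.37, SE 0.44, adjusted p = 0.000114). The difference between the polysomal and the monosomal change was -3.09 (SE 0.62, adjusted p = 0.041). That call was lost without any 1 of the 6 polysomal libraries, without empty vector monosomal replicate 2 or 3 and without mrps-5 RNAi monosomal replicate 2 (adjusted p = 0.0512 to 0.106). It was also lost with a filter of 5 CPM, by limma-voom, in a fit to these 12 libraries alone, with a prior count of 2 and with sample weights (0.081, 0.073, 0.391, 0.0585 and 0.435). A lowered mRNA does not show in these values, and the groups are called by their label. Whether double-stranded mrps-5 RNA of the feeding bacteria was counted with the worm transcript was not tested. Exchanged labels of the worm groups were not tested, and would turn the direction of each mrps-5 RNAi result given here. The call in total RNA was lost without empty vector total replicates 1, 2 or 3 (adjusted p = 0.102, 0.134 and 0.101) and without mrps-5 RNAi total replicates 2 (log2 change 1.40, adjusted p = 0.111) or 3 (adjusted p = 0.0901).

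In worm total RNA (3 against 3 libraries) yolk protein genes rose. vit-5 went from 4.63 ± 4.48 to 542 ± 423 CPM (log2 change 6.91, SE 0.86, adjusted p = 0.000347). vit-2 rose from 21.9 ± 10.8 to 844 ± 636 CPM (4.94, SE 0.55, adjusted p = 0.000117), and vit-6 from 63.1 ± 24.6 to 1640 ± 1230 CPM (4.31, SE 0.59, adjusted p = 0.000697). The glucuronosyltransferase gene ugt-19 rose from 8.81 ± 0.0199 to 108 ± 38.7 CPM (3.54, SE 0.28, adjusted p = 5.54e-06). In the same direction went cdr-4, from 17.2 ± 0.901 to 180 ± 76.6 CPM (3.29, SE 0.28, adjusted p = 1.26e-05), and the cytochrome P450 gene cyp-14A1, from 3.72 ± 0.481 to 30.4 ± 11.8 CPM (2.95, SE 0.5, adjusted p = 0.00406). On the other side, the transthyretin-like gene ttr-14 fell from 53.5 ± 16.5 to 0.351 ± 0.436 CPM (-7.98, SE 1.09, adjusted p = 0.000697). Its relative ttr-34 fell from 10.2 ± 2.92 to 0.112 ± 0.0652 CPM (-6.51, SE 0.99, adjusted p = 0.0016). The collagen gene col-63 fell from 709 ± 140 to 11.8 ± 13 CPM (-6.52, SE 0.64, adjusted p = 4.95e-05). These 9 calls held in each alternative fit and without each single library.

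By limma 164 genes were higher and 120 lower in total RNA of mrps-5 RNAi worms, of 14521 tested (1278 at an unadjusted p below 0.05, smallest adjusted p = 3.3e-06). Which side was larger depended on the fit: it was 130 higher and 142 lower with median-ratio size factors, 378 and 399 by limma-voom, and 163 and 213 without mrps-5 RNAi total replicate 2. By limma-voom the count was 777, which included all 284, and a fit to these 6 libraries alone called 1530, of which 265 were among the 284. The count dropped to 154, 108 and 133 without empty vector total replicates 1, 2 and 3, and to 124 and 136 without mrps-5 RNAi total replicates 1 and 3. The shared spread of all worm libraries holds the total RNA count down: in simulated data 70% of 2-fold and 82% of 4-fold changes were recovered, with 0% false among the calls.

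The mRNAs encoded by mitochondrial DNA were higher as a list in total RNA. Of 12, 8 passed the test over all genes, 11 passed it adjusted over the list alone and 12 had positive changes (median 1.24, adjusted p = 8.53e-21, or 0.0344 with an estimated correlation and 6.52e-21 to 0.0344 over the alternatives with all libraries). Among them, the cytochrome c oxidase subunits ctc-2 (1010 ± 51.2 to 3060 ± 332 CPM, log2 change 1.59, SE 0.23, adjusted p = 0.00128) and ctc-3 (1060 ± 65.6 to 2760 ± 273 CPM, log2 change 1.37, SE 0.22, adjusted p = 0.0026) rose most clearly. Mitochondrial chaperones and proteases rose as well (median 0.55, 8 of 20 higher and 0 lower, 10 higher adjusted over the list alone, adjusted p = 1.13e-14, or 0.00931 with an estimated correlation). Among them was the import channel gene timm-23 (64.9 ± 2.34 to 120 ± 2.53 CPM, log2 change 0.88, SE 0.12, adjusted p = 0.000697). Another member, hsp-6, the mitochondrial HSP70 and a usual reporter of the mitochondrial unfolded protein response, rose from 493 ± 31 to 1020 ± 41.9 CPM (1.05, SE 0.18, adjusted p = 0.00384, chosen after its value was seen). Of the response's transcription factor genes, atfs-1 was at 50.9 ± 2.59 and 76.9 ± 12.1 CPM (0.59, SE 0.19, adjusted p = 0.186). The worm ATF4 gene, atf-5, was at 31.6 ± 2.8 and 29 ± 3.28 CPM (-0.12, SE 0.22, adjusted p = 1).

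Glycolysis genes were higher (median 0.58, mean 0.36, 6 of 19 higher and 0 lower, 11 higher adjusted over the list alone, adjusted p = 2.08e-12, or 0.0364 with an estimated correlation). The phosphoglycerate mutase gene ipgm-1 was at 244 and 449 CPM (0.87, SE 0.13, adjusted p = 0.00129). Smaller shifts were called for mitochondrial ribosomal proteins other than mrps-5 (median 0.29, 68 of 68 positive, 2 higher, mrpl-45 by 0.78 and mrps-30 by 0.61, adjusted p = 3.23e-10). The nuclear-encoded respiratory chain (median 0.17, 0 of 64 called, adjusted p = 0.000467) and the TCA cycle (median 0.22, 0 of 19 called, 1 higher adjusted over the list alone, adjusted p = 0.000271) were called too. With an estimated correlation these 3 calls were lost (adjusted p = 0.249, 0.719 and 0.422).

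Lists tied to larval and adult development moved too. The vitellogenins had a median change of 3.26 (4 of 6 higher, 5 adjusted over the list alone, adjusted p = 7.66e-14, or 0.0344 with an estimated correlation). Cuticle collagens went both ways with a median of -1.05. Of 130, 7 were higher, for example col-147 from 216 to 833 CPM (1.98), and 20 lower, for example col-71 from 868 to 34.9 CPM (-4.89). Adjusted over the list alone, 19 were higher and 49 lower, and the list as a whole was called lower (adjusted p = 1.11e-10, lost with an estimated correlation, adjusted p = 0.0627). Without mrps-5 RNAi total replicate 1 its median was -0.69 (adjusted p = 2.6e-05). Major sperm protein and sperm genes had a median of -2.08 with 68 of 69 negative (adjusted p = 1.13e-14, lost with an estimated correlation, adjusted p = 0.277). Without mrps-5 RNAi total replicate 2 their median was -0.84 (adjusted p = 0.000282). Gene by gene, 0 of them passed the test over all genes or over the list alone. Germline and oocyte genes had a median of -0.30 (0 of 38 called, adjusted p = 0.000271, or 0.422 with an estimated correlation). Without mrps-5 RNAi total replicate 2 the median was 0.02 (adjusted p = 0.924).

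Detoxification enzymes had a median of 0.47, with 11 of 156 higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 1.05e-05, or 0.028 with an estimated correlation). Of these, ugt-2 rose from 9.36 to 63.3 CPM (2.72, SE 0.27, adjusted p = 5.18e-05) and ugt-44 fell (-0.74). ER chaperones (median -0.10, 1 of 17 lower, 3 adjusted over the list alone, adjusted p = 0.00129) included sel-1 of ER-associated degradation (-0.95, SE 0.19, adjusted p = 0.0137), and the list's median was -0.06 without empty vector total replicate 3 (adjusted p = 0.00289). The 26S proteasome (median -0.15, 0 of 31 called, adjusted p = 0.00153) and autophagy (median 0.18, 0 of 27 called, adjusted p = 0.0266) were also called. These 3 calls were lost with an estimated correlation (adjusted p = 0.242, 0.674 and 0.301). For each of the 14 lists called in total RNA the estimated correlation gave the highest adjusted p of the alternatives with all libraries. The autophagy call was also lost with median-ratio size factors (adjusted p = 0.0519) and without empty vector total replicate 2 (0.0517) or mrps-5 RNAi total replicate 2 (0.178).

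No call was made for 10 lists. Cytosolic ribosomal proteins had a median of 0.01 (mean -0.03, 0 of 82 called, adjusted p = 0.77), translation initiation and elongation factors one of -0.05 (adjusted p = 0.738, clu-1 rose by 1.03) and aminoacyl-tRNA synthetases one of -0.01 (mean 0.03, adjusted p = 0.705). C-type lectins had a median of 0.04 and a mean of -0.05 (adjusted p = 0.705, 3 of 125 higher, among them clec-5 and irg-4 by 1.32 and 1.25). Core histones (median -0.01, adjusted p = 0.441) and lipid synthesis (median 0.03, mean -0.21, adjusted p = 0.524 upward) were not called either. Intestinal proteases and lysozymes had a median of -0.06 (adjusted p = 0.524), with cpr-6 (-1.63) and lys-4 (-1.28) lower. Muscle structure (median 0.10, adjusted p = 0.0667), cytosolic heat shock proteins (median 0.17, adjusted p = 0.172) and neuropeptides (median 0.40, adjusted p = 0.16, nlp-24 rose by 1.07) complete the lists.

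The mitochondrial ribosomal RNAs, chosen after their values were seen, did not follow the mitochondrial mRNAs. In total RNA the small subunit rRNA MTCE.7 was at 50000 ± 1240 CPM with empty vector and 23800 ± 1790 CPM with mrps-5 RNAi (log2 change -1.07, adjusted p = 0.425). The large subunit rRNA MTCE.33 was at 29700 ± 580 and 40800 ± 2870 CPM (0.46, adjusted p = 1). In polysomal RNA MTCE.7 changed by -1.67 (adjusted p = 0.061) and MTCE.33 by -0.40 (adjusted p = 0.86). In monosomal RNA MTCE.7 fell from 407000 ± 167000 to 79100 ± 34700 CPM (-2.38, adjusted p = 0.00275), a call lost in a fit to the monosomal libraries alone, and MTCE.33 changed by -0.45 (adjusted p = 0.572). Within libraries, the log2 ratio of MTCE.7 to MTCE.33 was 0.75 ± 0.01 and -0.77 ± 0.19 in total RNA, 0.25 ± 0.23 and -1.01 ± 0.36 in polysomal RNA and 0.31 ± 0.15 and -1.61 ± 0.34 in monosomal RNA (empty vector, then mrps-5 RNAi, n = 3 each). That makes the ratio 2.89-fold, 2.4-fold and 3.79-fold lower, without overlap of the groups in any fraction, which a random split of 3 against 3 gives in 10% of cases. Ribosomal RNA had been depleted before sequencing, and a depletion that differs between the groups was not tested.

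**Figure D1:**
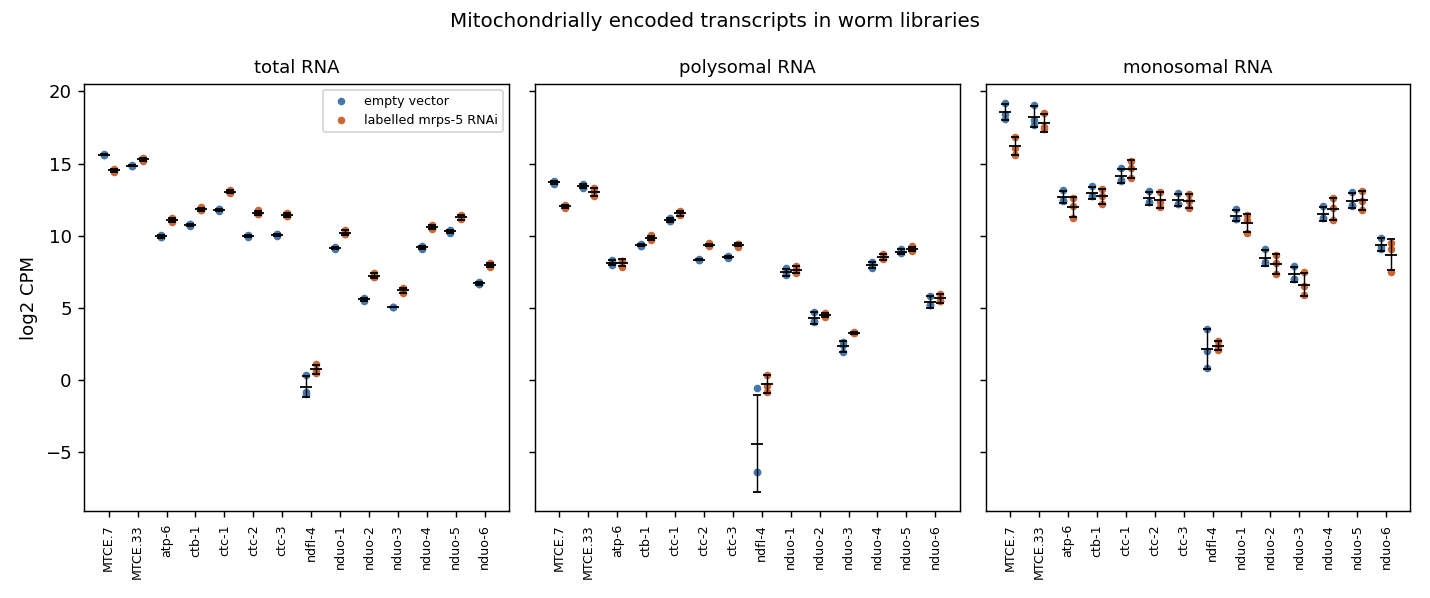
Mitochondrially encoded transcripts in the worm libraries, log2 CPM. MTCE.7 and MTCE.33 are the small and large subunit rRNAs, followed by 12 mRNAs. Points are libraries; bars show mean ± SD of 3.

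Polysomal RNA had similar extremes. With mrps-5 RNAi vit-5 rose from 11.9 ± 8.14 to 1150 ± 514 CPM (log2 change 6.91, SE 0.86, adjusted p = 0.000213). vit-2 rose from 44.3 ± 7.67 to 1750 ± 838 CPM (5.22, SE 0.55, adjusted p = 5.19e-05) and cdr-4 from 16.1 ± 0.437 to 201 ± 41.5 CPM (3.62, SE 0.28, adjusted p = 4.46e-06). C07G1.7 went from 0.0455 ± 0.0788 to 17.7 ± 6.8 CPM (adjusted p = 0.000296). The genes ttr-14, ttr-34 and ule-4 had no reads in any of the 3 mrps-5 RNAi polysomal libraries and were at least 339-fold, 72.9-fold and 81.7-fold lower than with empty vector, against a floor of 3 reads per library. By limma 202 genes were higher and 150 lower (352 of 14521, and 1790 at an unadjusted p below 0.05). The balance was 91 and 92 without empty vector polysomal replicate 3, and 103 and 142 or 94 and 96 without mrps-5 RNAi polysomal replicates 1 or 2. limma-voom called 758, with 341 shared, and a fit to these 6 libraries alone 538, with 279 shared. Leaving out 1 library gave 185 and 183 calls without empty vector polysomal replicates 2 and 3, and 190 and 184 without mrps-5 RNAi polysomal replicates 2 and 3.

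Of the genes called in total RNA, 124 were also higher and 96 also lower in polysomal RNA (2.28 and 1.24 expected by chance), and 0 were called in opposite directions. This overlap of 220 was 97 to 142 without 1 empty vector total library, mrps-5 RNAi total replicate 1 or 3, or replicate 2 or 3 of either polysomal group.

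Among the lists in polysomal RNA, 5 were called higher. Vitellogenins had a median of 3.75 (4 of 6 higher, adjusted p = 1.65e-11) and glycolysis one of 0.47 (6 of 19 higher, 11 adjusted over the list alone, adjusted p = 1.09e-09). Mitochondrial chaperones and proteases had a median of 0.49 (8 of 20 higher, 9 adjusted over the list alone, adjusted p = 5.3e-08). Detoxification enzymes (median 0.40, 9 of 156 higher and 1 lower, 12 and 2 adjusted over the list alone) and the mtDNA-encoded mRNAs (median 0.49, 1 of 12 higher, 4 adjusted over the list alone) both had an adjusted p = 0.000106. Called lower were sperm genes (median -1.90, 0 of 69 called, adjusted p = 1.61e-10) and the 26S proteasome (median -0.23, 0 of 31 called, adjusted p = 0.000223). Collagens were called lower too (median -0.66, mean -1.41, or a median of -0.63 with genes at 0 set at their bound, adjusted p = 3.1e-05), with 9 of 130 higher and 21 lower (20 and 42 adjusted over the list alone). Without mrps-5 RNAi polysomal replicate 1 the collagen median was -0.17 (adjusted p = 0.0154). All 8 calls were lost with an estimated correlation, with the lowest adjusted p at 0.0574 for both the chaperones and the detoxification enzymes. hsp-6 rose from 909 ± 97.1 to 1680 ± 96.8 CPM (0.89, SE 0.18, adjusted p = 0.01). The mitochondrial ctc-2 rose from 325 ± 7.75 to 655 ± 47.3 CPM (1.01, SE 0.23, adjusted p = 0.0315). Cytosolic ribosomal proteins stayed without a call (median 0.00, 0 of 82 called, adjusted p = 0.771), as did translation factors (median -0.14, adjusted p = 0.0519, clu-1 rose by 0.79).

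Monosomal RNA gave more calls, but with a weaker error control. R08F11.4, at 0 reads in all 3 empty vector libraries and 10.7 ± 3.77 CPM with mrps-5 RNAi, was at least 42.9-fold higher. pes-8 and the collagen genes col-181 and col-88, at 0 in all 3 mrps-5 RNAi libraries, were at least 92.7-fold, 90.5-fold and 75-fold lower. These 4 genes (adjusted p = 2.91e-06, 2.93e-05, 8.26e-05 and 8.82e-05) were called in each alternative and without each library. The detoxification gene ugt-2 rose from 4 ± 1.03 to 51.6 ± 18.2 CPM (3.65, SE 0.27, adjusted p = 2.54e-06). timm-23 rose from 68.8 ± 12.3 to 170 ± 11.6 CPM (1.32, SE 0.12, adjusted p = 9.45e-06). In all, 780 genes were higher and 901 lower (1681 of 14521, 4228 at an unadjusted p below 0.05, limma-voom 1094, with 1034 shared). More were higher than lower with a filter of 5 CPM (762 and 607) and without empty vector monosomal replicates 1 (1160 and 864) or 3 (709 and 695). A fit to these 6 libraries alone called 196 (195 of the 1681). With 200 simulated changes 73.9% of the larger fit's calls and 17.1% of the smaller's were false, which gives no share of the 1681. With polysomal RNA 156 higher and 104 lower calls were shared (10.9 and 9.31 expected) and 0 were opposite. This overlap of 260 was 142 to 150 without replicate 2 or 3 of either polysomal group, and 57 in fits to each fraction alone.

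Of the 24 lists 15 were called in monosomal RNA, and 0 with an estimated correlation (lowest adjusted p = 0.0829). Among them were vitellogenins (median 3.66, 4 of 6 higher, adjusted p = 5.44e-06) and sperm genes (median -2.52, 6 of 69 lower, adjusted p = 4.74e-06). The sperm median was -4.06 and -1.04 without mrps-5 RNAi monosomal replicates 1 and 2 (adjusted p = 1.1e-07 and 0.00269). Glycolysis had a median of 0.67 (13 of 19 higher, 15 higher and 1 lower adjusted over the list alone, adjusted p = 2.67e-10). Mitochondrial chaperones had a median of 0.58 (9 of 20 higher, 12 adjusted over the list alone, adjusted p = 1.8e-08). The respiratory chain (median 0.47, 14 of 64 higher, 29 higher and 1 lower adjusted over the list alone, adjusted p = 4.8e-13) and cytosolic ribosomal proteins (median 0.30, 0 of 82 called, adjusted p = 1.8e-08) were called higher too. Without empty vector monosomal replicate 2 these 2 medians were 0.23 and 0.13, and without mrps-5 RNAi monosomal replicate 3 that of the ribosomal proteins was 0.15, all still called. The mtDNA-encoded mRNAs were not called (median -0.17, adjusted p = 0.434). Collagens (median -0.95, or -0.68 with genes at 0 set at their bound, 20 of 130 higher and 41 lower, adjusted p = 0.0143) lost their call without mrps-5 RNAi monosomal replicate 1 (median -0.67, adjusted p = 0.167).

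**Figure D2:**
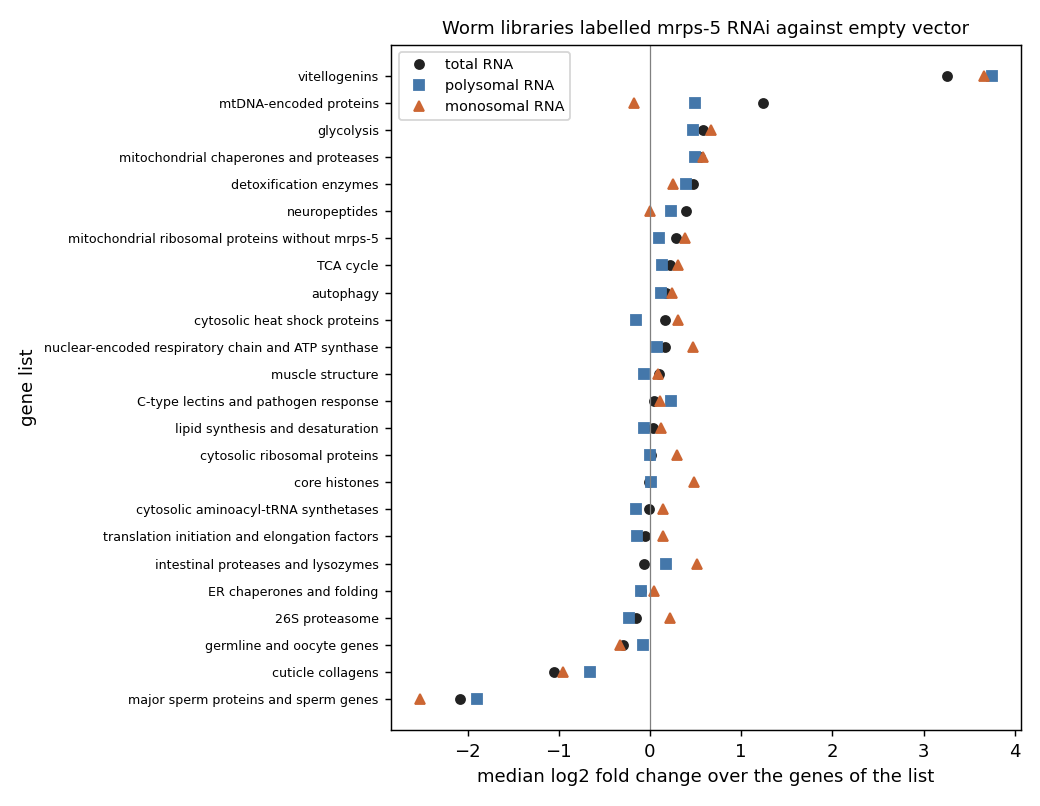
Median log2 change of each worm gene list in libraries labelled mrps-5 RNAi against empty vector, for total, polysomal and monosomal RNA (3 libraries per group).

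The shift of RNA between fractions with mrps-5 RNAi was tested as an interaction. For polysomal against total RNA no gene passed limma (0 of 14521, 78 at an unadjusted p below 0.05, limma-voom 0, smallest adjusted p = 1). Without a filter 24 passed, with sample weights 15 and with the genes over 1 percent of reads left out before scaling 1. In simulated data 59% of 2-fold and 73% of 4-fold changes of this kind were recovered. As a list, the mtDNA-encoded mRNAs rose less in polysomal than in total RNA (median -0.78, mean -0.49, 11 of 12 negative, 1 lower adjusted over the list alone, adjusted p = 9.71e-15). Cytosolic heat shock proteins shifted the same way (median -0.42, 10 of 10 negative, adjusted p = 5.78e-05), as did mitochondrial ribosomal proteins (median -0.18, adjusted p = 3.08e-06). Of 11 list calls at the preset correlation, 0 remained with an estimated one (adjusted p = 0.186, 0.064 and 0.562 for these 3 lists).

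For monosomal against total RNA the interaction was called for 12 genes upward and 37 downward by limma (1133 at an unadjusted p below 0.05, limma-voom 28), but for 71 upward and 69 downward without empty vector monosomal replicate 1. The transthyretin-like gene ttr-41 (-1.96, SE 0.3, adjusted p = 0.00874) was among those that rose less or fell more in monosomal RNA, a call lost by limma-voom (0.121). In a fit to the 12 libraries of the contrast 2 genes were called, both upward, and ttr-41 was not (0.1). Without single libraries the count was 11, 10 and 11 (empty vector total 1, 2 and 3), 20, 20 and 10 (mrps-5 RNAi total), 140, 93 and 71 (empty vector monosomal) and 429, 110 and 133 (mrps-5 RNAi monosomal). The mtDNA-encoded list had a median of -1.49 (2 of 12 lower, 10 adjusted over the list alone, adjusted p = 3.65e-14). Intestinal proteases had one of 0.57 (0 of 32 called, adjusted p = 1.27e-10). Both were lost with an estimated correlation (adjusted p = 0.207 for both).

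For polysomal against monosomal RNA 39 interactions were positive and 11 negative by limma (1484 at an unadjusted p below 0.05, limma-voom 14), and 83 and 85 without empty vector monosomal replicate 1. The gene ttr-41 (2.01, SE 0.3, adjusted p = 0.00619) was among the first and exos-7, of the RNA exosome (-1.60, SE 0.27, adjusted p = 0.0145), among the second. A fit to the 12 libraries of the contrast called 0, limma-voom ended the call of ttr-41 (0.127) and sample weights that of exos-7 (0.232). Single libraries moved the count to 30 and 32 without empty vector polysomal replicates 1 and 3, and to 29 and 29 without mrps-5 RNAi polysomal replicates 1 and 2. The count was 168, 104 and 85 without empty vector monosomal replicates 1, 2 and 3 and 511, 120 and 151 without mrps-5 RNAi monosomal replicates 1, 2 and 3. Lists shifted toward the monosomal fraction were the 26S proteasome (median -0.45, 31 of 31 negative, adjusted p = 8.71e-09), the respiratory chain (median -0.36, 60 of 64 negative, adjusted p = 1.08e-11) and cytosolic ribosomal proteins (median -0.31, 75 of 82 negative, adjusted p = 7.14e-10). Without empty vector monosomal replicate 2 their medians were -0.11, -0.11 and -0.12 (adjusted p = 0.00682, 0.00262 and 0.00368), and without mrps-5 RNAi monosomal replicate 3 that of the ribosomal proteins was -0.17. These calls too were lost with an estimated correlation (adjusted p = 0.492 for each).

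In empty vector worms the fractions themselves differed in composition. Against total RNA, polysomal RNA held more prmt-1, an arginine methyltransferase gene (180 ± 7.4 to 660 ± 73.1 CPM, log2 change 1.87, SE 0.13, adjusted p = 3.12e-07). It held less K09F6.10 (21 ± 0.524 to 0.307 ± 0.214 CPM, log2 change -6.25, SE 0.71, adjusted p = 4.18e-05). The gene atf-5 was lower in polysomal RNA (31.6 ± 2.8 to 10.9 ± 2.01 CPM, log2 change -1.55, SE 0.22, adjusted p = 0.000198). Higher lists were the 26S proteasome (median 1.04, 29 of 31 higher, adjusted p = 1.22e-23), mitochondrial ribosomal proteins (0.90, 47 of 68, adjusted p = 1.83e-24) and aminoacyl-tRNA synthetases (0.85, 20 of 20, adjusted p = 2.13e-20). Translation factors (0.84, 29 of 44, adjusted p = 2.83e-22) and the respiratory chain (0.79, 37 of 64, adjusted p = 5.48e-21) were higher as well. Lower were the mtDNA-encoded mRNAs (-1.47, 10 of 12, adjusted p = 5.28e-12) and neuropeptides (-1.27, 10 of 88, adjusted p = 4.46e-06). All 7 calls were lost with an estimated correlation (adjusted p = 0.083, 0.058, 0.058, 0.058, 0.166, 0.083 and 0.083). With the rotation test fry all 7 were kept (highest adjusted p = 0.00417). By limma 1452 genes were higher and 811 lower (3834 at an unadjusted p below 0.05, limma-voom 3574). Median-ratio size factors moved the median of all genes by -0.14, to 1078 higher and 1055 lower. Without a filter 1516 were higher and 2111 lower and with sample weights 2974 and 3005, and the count dropped to 1420, 1464 and 1485 without empty vector total replicates 1, 2 and 3.

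Against monosomal RNA, polysomal RNA held less of the rRNA gene rrn-2.1 (77000 ± 37700 to 2050 ± 598 CPM, log2 change -5.16, SE 0.38, adjusted p = 8.17e-08) and of atf-5 (70.6 ± 12.3 to 10.9 ± 2.01 CPM, -2.70, SE 0.22, adjusted p = 1.99e-07). The mtDNA-encoded mRNAs were lower (median -3.95, 12 of 12 lower, adjusted p = 1.03e-19, or 0.0341 with an estimated correlation). Among them ctc-2 went from 6340 ± 2090 to 325 ± 7.75 CPM (-4.24, SE 0.23, adjusted p = 9.76e-09). It held more hsp-4, the ER chaperone BiP (189 ± 21.8 to 524 ± 37.3 CPM, log2 change 1.48, SE 0.11, adjusted p = 1.08e-07). Intestinal proteases (median 1.78, 29 of 32 higher), C-type lectins (1.65, 36 of 125 higher and 3 lower) and ER chaperones (1.03, 14 of 17 higher) were higher. So were detoxification enzymes (1.35, or 1.30 with genes at 0 set at their bound, 55 of 156 higher and 3 lower). These 4 lists were called with an estimated correlation too (adjusted p = 0.0278 for each). Cytosolic ribosomal proteins were lower in polysomal RNA (median -1.01, 74 of 82 lower, adjusted p = 7.53e-32, lost with an estimated correlation, adjusted p = 0.138). In total 2786 genes were higher and 1632 lower by limma (5762 at an unadjusted p below 0.05, limma-voom 4765). A fit to the 6 libraries alone called 3177, and median-ratio size factors moved the median of all genes by -0.13.

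In mouse liver total RNA (3 against 3 libraries) no gene passed between doxycycline and amoxicillin by limma (0 of 14030, 337 at an unadjusted p below 0.05, limma-voom 0, smallest adjusted p = 1). In simulated data 65% of 2-fold and 93% of 4-fold changes were recovered. Cholesterol synthesis and uptake genes were higher as a list. Sc5d was at 301 ± 27.1 CPM with amoxicillin and 357 ± 53.6 CPM with doxycycline (log2 change 0.24, SE 0.17, adjusted p = 1). The list's median was 0.56, with 24 of 25 genes positive and 10 higher adjusted over the list alone (adjusted p = 1.18e-25, lost with an estimated correlation, adjusted p = 0.211, and 7.14e-27 to 0.523 over the alternatives with all libraries). Red blood cell genes (median -0.83, 5 of 5 negative, 4 lower adjusted over the list alone, adjusted p = 1.84e-10), such as Hbb-bs (175 ± 67.6 and 93.2 ± 31.8 CPM), were lower. Kupffer cell markers (median -0.50, 13 of 15 negative, 1 lower adjusted over the list alone, adjusted p = 1.61e-11), such as Clec4f (111 ± 31.8 and 79.7 ± 13.4 CPM), were lower too, with a median of -0.26 without amoxicillin total replicate 2 (adjusted p = 8.36e-05). Fatty acid synthesis (median 0.16, adjusted p = 4.96e-05) and xenobiotic P450s and conjugation (median 0.21, 46 of 59 positive, adjusted p = 7e-05) were higher, with Scd1 at 5830 ± 1230 and 7630 ± 716 CPM (0.40, SE 0.28, adjusted p = 1). Without doxycycline total replicate 3 the median of the P450 list was 0.12 (adjusted p = 0.00921). Estimated correlations removed these 4 calls (adjusted p = 0.211, 0.244, 0.244 and 0.413).

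Another 10 lists were called at the preset correlation in mouse total RNA and depended on single libraries. Without amoxicillin total replicate 2 the call ended for major urinary proteins (median -0.61, and -0.36 without it, adjusted p = 0.0595), the respiratory chain (-0.12 and -0.01, adjusted p = 0.552) and mitochondrial ribosomal proteins (-0.10 and -0.05, adjusted p = 0.0505). It also ended for the 26S proteasome (-0.12 and 0.00, adjusted p = 1), mitochondrial chaperones (-0.07 and -0.02, adjusted p = 0.448) and the mtDNA-encoded mRNAs (0.13 and -0.13, adjusted p = 0.999). Circadian clock genes (0.12 and 0.08, adjusted p = 0.428) and fatty acid oxidation (0.05 and 0.06, adjusted p = 0.116) lost it as well. The proteasome, chaperone, mtDNA and clock calls also ended without doxycycline total replicate 1 (adjusted p = 0.074, 0.0622, 0.233 and 0.245). Without amoxicillin total replicate 3 the clock and fatty acid oxidation calls ended (adjusted p = 0.0519 and 0.0591). The mtDNA call ended without doxycycline total replicate 3 (adjusted p = 0.0559) and the fatty acid oxidation call without doxycycline total replicate 2 (median -0.02, adjusted p = 0.448). Bile acid synthesis (0.12) was no longer called without amoxicillin total replicates 1 and 3 or doxycycline total replicate 2 (adjusted p = 0.097, 0.537 and 0.26). Endothelial markers (-0.12) were not called without amoxicillin total replicate 3 or doxycycline total replicate 2 (adjusted p = 0.653 and 0.473). Other medians moved while the call held: without amoxicillin total replicate 3 to -0.94 for major urinary proteins, -0.22 for the proteasome and 0.32 for the mtDNA-encoded mRNAs. These mRNAs were at 0.30 and 0.28 without amoxicillin total replicate 1 or doxycycline total replicate 2. Endothelial markers were at -0.21 without amoxicillin total replicate 1, and fatty acid oxidation at 0.03 and 0.08 without amoxicillin total replicate 1 or doxycycline total replicate 3. None of these 10 was called with an estimated correlation (lowest adjusted p = 0.401).

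The other 14 lists tested were not called in mouse total RNA. ATF4 and integrated stress response targets had a median of -0.06 and a mean of 0.08 (0 of 22 called, adjusted p = 0.803). For cytosolic ribosomal proteins (median -0.05) the adjusted p was 0.0727, for translation factors (0.00) 0.977, for aminoacyl-tRNA synthetases (0.01) 0.977 and for cytosolic heat shock proteins (-0.07) 0.0922. For ER chaperones (0.04, 1 higher adjusted over the list alone) it was 0.0922, for NRF2 targets (0.06) 0.11, for autophagy and lysosome (-0.04) 0.378 and for gluconeogenesis (-0.03) 0.734. For acute phase proteins (-0.04, mean 0.07) it was 0.977, for interferon-stimulated genes (-0.02) 0.718 and for cell cycle (-0.04) 0.254. For secreted hepatocyte proteins (0.01) it was 0.948 and for stellate cell markers (0.12) 0.468. Atf4 was at 69 ± 4.8 and 65.5 ± 3.41 CPM (-0.08, SE 0.12). Atf5 was at 91.2 ± 24.6 and 94.5 ± 5.4 CPM (0.08, SE 0.16) and Ddit3 at 5.23 ± 0.411 and 5.11 ± 1.05 CPM (-0.05, SE 0.6), each with an adjusted p = 1.

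In mouse polysomal RNA 1 gene was higher and 22 were lower with doxycycline by limma (23 of 14030, 1154 at an unadjusted p below 0.05, limma-voom 2). Gm25395 fell from 334 ± 32.4 to 106 ± 62.5 CPM (-1.82, SE 0.3, adjusted p = 0.033). The small Cajal body RNA gene Scarna6 fell from 230 ± 43.3 to 93.4 ± 34.6 CPM (-1.34, SE 0.22, adjusted p = 0.0302) and the spectrin gene Sptbn1 from 83 ± 8.71 to 53.4 ± 3.41 CPM (-0.63, SE 0.1, adjusted p = 0.0257). These 3 calls were lost under a filter of 5 CPM, in a fit to the 6 libraries alone, with a prior count of 2 and with sample weights, and each was lost without doxycycline polysomal replicate 2. Sptbn1 was also lost by limma-voom (adjusted p = 0.184). Gm25395 was also lost without amoxicillin polysomal replicate 2 or 3, and Scarna6 without amoxicillin polysomal replicate 1 or 3 or doxycycline polysomal replicate 1. The count was 45 and 46 without amoxicillin polysomal replicates 1 and 3, and 48, 40 and 68 without doxycycline polysomal replicates 1, 2 and 3. Of all genes, 0 were called in both mouse fractions.

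Cholesterol synthesis and uptake genes were higher as a list in polysomal RNA too. All 25 genes were positive, the median was 0.72 and 17 were higher adjusted over the list alone (adjusted p = 5.34e-23, lost with an estimated correlation, adjusted p = 0.322, and 5.32e-25 to 0.322 over the alternatives with all libraries). Per library, the list's median log2 CPM was 6.17, 5.98 and 5.44 with amoxicillin and 6.18, 6.40 and 6.52 with doxycycline in polysomal RNA. In total RNA it was 6.25, 6.07 and 5.45 against 6.26, 6.70 and 6.69. The mtDNA-encoded mRNAs had a median of 0.61 (mean 1.07, 5 of 12 higher adjusted over the list alone, adjusted p = 0.000259, or 0.453 with an estimated correlation, and a median of 0.40 without doxycycline polysomal replicate 2, adjusted p = 0.04). mt-Co3 was at 852 ± 522 and 2320 ± 524 CPM (1.72, SE 0.46, adjusted p = 0.328) and mt-Co1 at 7370 ± 912 and 8010 ± 1800 CPM (0.10, SE 0.24, adjusted p = 0.945). Cytosolic ribosomal proteins (median -0.16, 75 of 79 negative, adjusted p = 1.16e-07) and endothelial markers (-0.36, 13 of 14 negative, adjusted p = 6.44e-06) were lower, and lost their calls with an estimated correlation (adjusted p = 0.604 and 0.453). The first median was -0.08 without amoxicillin polysomal replicate 2 (adjusted p = 0.0182), and the second -0.17 and -0.23 without amoxicillin or doxycycline polysomal replicate 1 (adjusted p = 0.0164 and 0.0182). Atf4 (0.04, SE 0.12, adjusted p = 0.955), Atf5 (-0.23, SE 0.16, adjusted p = 0.762) and Ddit3 (3.81 ± 1.14 and 1.83 ± 1.29 CPM, log2 change -1.47, SE 0.6, adjusted p = 0.537) did not pass.

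**Figure D3:**
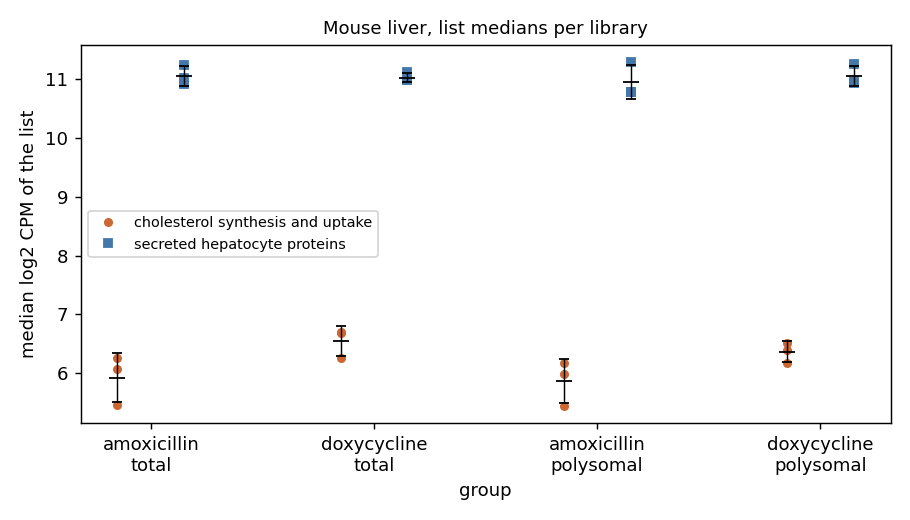
Median log2 CPM over the genes of 2 lists in each mouse liver library, by antibiotic and fraction. Points are libraries; bars show mean ± SD of 3.

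The difference between polysomal and total RNA did not change with doxycycline for any gene by limma (0 of 14030, 408 at an unadjusted p below 0.05, limma-voom 0, smallest adjusted p = 0.111). Of simulated changes, 56% of 2-fold and 92% of 4-fold ones were recovered. Without doxycycline polysomal replicates 2 and 3 the count was 10 and 4. At the preset correlation 11 lists were called, among them the respiratory chain (median 0.10, 61 of 75 positive, adjusted p = 0.000247) and cholesterol synthesis (median 0.19, 20 of 25 positive, adjusted p = 0.0416). With an estimated correlation 0 were called (adjusted p = 0.626 for both). The respiratory chain call ended without amoxicillin total replicate 2 (median -0.02, adjusted p = 0.888), while without amoxicillin total replicate 1 the median was 0.17. That of cholesterol synthesis was 0.29 without amoxicillin total replicate 3. The cholesterol call ended without amoxicillin total replicates 1 and 2, doxycycline total replicate 1 or doxycycline polysomal replicate 3 (0.323, 0.125, 0.365 and 0.684), and without amoxicillin polysomal replicate 3 its median was -0.07 (adjusted p = 0.718).

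Polysomal against total RNA in amoxicillin livers differed most for Neat1, a long RNA retained in the nucleus, which was at 9590 ± 2230 CPM in total and 13.5 ± 4.79 CPM in polysomal RNA (-9.51, SE 0.22, adjusted p = 1.53e-11). Higher in polysomal RNA were Scarna6 (29.9 ± 1.61 to 230 ± 43.3 CPM, log2 change 2.92, SE 0.22, adjusted p = 1.21e-06) and the histone gene Hist1h4b (4.63 ± 1.45 to 28.8 ± 2.03 CPM, 2.68, SE 0.22, adjusted p = 1.91e-06). The respiratory chain (median 1.07, 72 of 75 higher, adjusted p = 2.23e-32), mitochondrial ribosomal proteins (0.83, 63 of 80 higher and 2 lower, adjusted p = 6.18e-18) and the 26S proteasome (0.78, 29 of 35 higher, adjusted p = 2.78e-12) were higher. These 3 calls were lost with an estimated correlation (adjusted p = 0.137, 0.136 and 0.178). The mtDNA-encoded mRNAs were lower (median -1.2, 7 of 12 lower, adjusted p = 0.0266), mt-Co2 from 999 ± 249 to 76.4 ± 59.5 CPM (-4.31, SE 0.69, adjusted p = 0.000275). Its list lost the call with an estimated correlation (adjusted p = 0.496) and without amoxicillin total replicates 1 and 3 (0.0993 and 0.0665). By limma 2625 genes were higher and 3231 lower of 14030 (6900 at an unadjusted p below 0.05, limma-voom 6100), but 2618 were higher and 2438 lower with a filter of 5 CPM.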

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

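The splits of the libraries and the fits with a prior count of 2 or sample weights, named in this part, were chosen only after the results were seen. For the genes given here a test of the difference itself, the interaction term in limma, found that the change with mrps-5 RNAi differed between RNA fractions of the worm. Each value is the difference of 2 log2 changes, from 3 libraries per group.

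Between monosomal and total RNA the change with mrps-5 RNAi differed for 49 genes. It was higher in monosomal RNA for R08F11.4 (7.02, adjusted p = 0.0106), faah-3 (1.53, adjusted p = 0.0251), ilys-5 (1.33, adjusted p = 0.0235) and ZK1193.2 (1.12, adjusted p = 0.0396). It was lower there for nspc-17 (-8.97, adjusted p = 0.00232), F48C5.2 (-8.5, adjusted p = 0.00232), ncx-6 (-7.68, adjusted p = 0.0047), cutl-28 (-6.65, adjusted p = 0.0436) and mltn-3 (-6.3, adjusted p = 0.0393). The mitochondrial mRNAs nduo-2 (-2.04, adjusted p = 0.0461) and ctc-2 (-1.70, adjusted p = 0.0369) and the gene ttr-41 (-1.96, adjusted p = 0.00874) were lower there too. With mrps-5 RNAi, nspc-17, F48C5.2 and ncx-6 had 0 reads in all 3 monosomal libraries, as R08F11.4 had with empty vector, so their values depend on the prior count and are no bounds.

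In a fit to the 12 libraries of this contrast 2 genes were called and none of these 12 was (adjusted p = 0.0888 to 0.203). With a prior count of 2 the count was 8 and only nspc-17, F48C5.2 and ttr-41 of these 12 were called (the others 0.0624 to 0.129). By limma-voom R08F11.4, faah-3, ZK1193.2, cutl-28, mltn-3 and ttr-41 were not called (0.0546 to 0.179), and with a filter of 5 CPM ZK1193.2, cutl-28, mltn-3, nduo-2 and ctc-2 (0.0609 to 0.0864). With sample weights R08F11.4, faah-3, ilys-5, ZK1193.2, cutl-28, mltn-3 and nduo-2 were not (0.064 to 0.26). The call of nduo-2 also ended with median-ratio size factors (0.0563) and without the most abundant genes (0.0509). The count was 10 to 429 with 1 library left out, and 8 with a block on the replicate number within each treatment. The calls of nspc-17, F48C5.2, ncx-6 and ttr-41 held without any single library. That of R08F11.4 ended without empty vector total replicate 2 or 3 or mrps-5 RNAi total replicate 3 (adjusted p = 0.0585, 0.0669 and 0.0615). The other 7 calls ended without any 1 of the 3 empty vector total libraries (adjusted p = 0.067 to 0.162) and without mrps-5 RNAi total replicate 3 (0.0812 to 0.133). They ended as well, except for cutl-28, without mrps-5 RNAi total replicate 1 and, except for ZK1193.2, without replicate 2 (0.0565 to 0.156). Without empty vector monosomal replicate 2 the calls of cutl-28 and nduo-2 ended (0.0543 and 0.0592), and without replicate 3 those of cutl-28 and mltn-3 (0.0844 and 0.0613). Of 100 splits of these libraries 26 gave at least 49 genes, with 355 in the highest of the others. These splits mix the treatments within a fraction, so a split that differs between the fractions carries the treatment effect into the difference. They therefore cannot decide on chance, which is not excluded.

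Between polysomal and monosomal RNA the change with mrps-5 RNAi differed for 50 genes. It was higher in polysomal RNA for nspc-17 (9.04, adjusted p = 0.00187), ncx-6 (7.95, adjusted p = 0.0034), cutl-28 (6.94, adjusted p = 0.0345), unc-57 (2.15, adjusted p = 0.0472) and ttr-41 (2.01, adjusted p = 0.00619). It was lower there for R08F11.4 (-6.93, adjusted p = 0.0093), mrps-5 (-3.09, adjusted p = 0.041), exos-7 (-1.60, adjusted p = 0.0145) and F46C5.9 (-0.83, adjusted p = 0.041). As above, the values of nspc-17, ncx-6 and R08F11.4 rest on groups with 0 reads in all 3 libraries.

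A fit to the 12 libraries of this contrast called 0 genes, with an adjusted p of 0.391 to 0.621 for these 9. With a prior count of 2 the count was 15, without cutl-28, unc-57, R08F11.4, mrps-5 and F46C5.9 (0.0585 to 0.123). By limma-voom these 5 and ttr-41 were not called (0.073 to 0.2), and with sample weights these 5 and exos-7 (0.195 to 0.554). The first 2, mrps-5 and F46C5.9 were not called with a filter of 5 CPM (0.0538 to 0.0894), nor unc-57 and F46C5.9 without a filter (0.0562 for both). The count was 29 to 511 with 1 library left out, and 12 with a block on the replicate number within each treatment. The calls of nspc-17, ncx-6, ttr-41, R08F11.4 and exos-7 held without any single library. Those of cutl-28 (adjusted p = 0.0579 to 0.104), F46C5.9 (0.0515 to 0.106) and mrps-5 (0.0515 to 0.106) ended without any 1 of the 6 polysomal libraries. They also ended without empty vector monosomal replicate 3 for cutl-28 and mrps-5 (0.0567 and 0.0512), and without empty vector monosomal replicate 2 or mrps-5 RNAi monosomal replicate 2 for mrps-5 (0.064 and 0.0523). The call of unc-57 ended without empty vector polysomal replicate 2 or 3, empty vector monosomal replicate 2 or any 1 of the 3 mrps-5 RNAi polysomal libraries (0.0644 to 0.131). Of 100 splits of these libraries 26 gave at least 50 genes, with 496 in the highest of the others, so chance is not excluded here either.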

How the results depend on the processing

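A prior count of 2, sample weights and a fit without the monosomal libraries were chosen after seeing the data, and so was the test on splits of libraries. The size factors of DESeq2 were not run as such, since the values are on a log scale, and median-ratio factors computed from the recovered reads took their place. Where leaving out a library leaves 2 in a group, the spread of all libraries is shared.

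Of 122 results for single genes, tried in 2058 alternatives, 1751 outcomes kept direction and call, 307 kept the direction but lost the call and 0 reversed. Of 154 list calls, tried in 2438 alternatives, 2009 kept the call and the direction of the list test, 422 lost the call and 7 reversed in that direction. The 7 reversals each came with 1 library left out, and the range of the median in brackets is that of all such fits. They were the worm 26S proteasome in monosomal RNA without empty vector replicate 2 (median -0.16, range -0.16 to 0.44) and germline genes in the polysomal against total difference without mrps-5 RNAi total replicate 2 (-0.11, range -0.11 to 0.36). In mouse total RNA they were the 26S proteasome (0.00, range -0.22 to 0.00) and the mtDNA-encoded mRNAs (-0.13, range -0.13 to 0.32) without amoxicillin replicate 2. In mouse polysomal RNA they were ER chaperones without amoxicillin replicate 3 (-0.07, range -0.07 to 0.32). Without that last library cholesterol synthesis (-0.07, range -0.07 to 0.29) and major urinary proteins (-0.06, range -0.06 to 1.07) also reversed in the polysomal against total difference. In 6 further fits without 1 library the median alone turned its sign. In worm these were germline genes in total RNA without mrps-5 RNAi replicate 2 (0.02), the TCA cycle for monosomal against total without empty vector monosomal replicate 2 (-0.01) and heat shock proteins for polysomal against total with empty vector without polysomal replicate 3 (-0.01, still called). In mouse they were fatty acid oxidation in total RNA without doxycycline replicate 2 (-0.02), and Kupffer markers and the respiratory chain for the difference without amoxicillin total replicate 2 (-0.02 for both). The median of no called list changed sign with median-ratio size factors or with the most abundant genes left out before scaling.

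With a correlation estimated for each list, the number of lists called went from 14 to 5 in worm total RNA and from 18 to 5 for polysomal against monosomal RNA with empty vector. It went to 0 in worm polysomal RNA, worm monosomal RNA, the 3 worm differences between fractions, polysomal against total RNA with empty vector, and all 4 mouse comparisons. With the rotation test fry it was 6 in worm total RNA, 4 in polysomal RNA and 6 in monosomal RNA. It was 0 in the 3 worm differences, in both mouse fractions and in their difference. Over the alternatives with all libraries, the estimated correlation gave the highest adjusted p for every called list of 8 comparisons. In the worm polysomal against total difference, mouse total RNA and the mouse difference fry gave the highest, up to 0.989, 0.913 and 0.71. In the worm monosomal against total difference it did so too, up to 0.974, except for the mtDNA-encoded mRNAs (0.207, fry 0.0581), ER chaperones (0.384, fry 0.348) and intestinal proteases (0.207, fry 0.197). Which correlation fits these lists was not tested.

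limma-voom called 777 genes in worm total RNA (limma on the deposited values 284), 758 in polysomal RNA (352) and 1094 in monosomal RNA (1681). It called 28 for the monosomal against total difference (49), 14 for the polysomal against monosomal difference (50), 3574 for polysomal against total RNA with empty vector (2263) and 2 in mouse polysomal RNA (23). Between worm total and polysomal RNA 499 of its calls were shared (220). Fits to the libraries of a contrast alone called 1530, 538 and 196 genes in worm total, polysomal and monosomal RNA. For the monosomal against total and polysomal against monosomal differences they called 2 and 0, for polysomal against total RNA 5460 and in mouse polysomal RNA 8. Their overlaps were 394 for total with polysomal and 57 for polysomal with monosomal RNA (260), and 13 lists were called in polysomal RNA (8). Here the spread is that of fewer libraries: the total RNA groups have a median SD of 0.08 and 0.14 and the monosomal ones of 0.37 and 0.34.

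Without a filter 24 genes were called for the worm polysomal against total difference (0 with it), 83 for monosomal against total, 3627 for polysomal against total with empty vector, and 7 lists for the mouse difference (11). With a filter of 5 CPM the counts were 13 for monosomal against total, 11 for polysomal against monosomal and 0 in mouse polysomal RNA. Leaving out genes over 1 percent of reads before scaling gave 1 gene for the worm polysomal against total difference. A block on the replicate number moved 26 of 28 results by at most 1.5 times. The exceptions were the monosomal against total difference (26 genes, and 8 with a block within each treatment) and the polysomal against monosomal difference (33 and 12). With the block within each treatment R08F11.4, exos-7, cutl-28, unc-57 and F46C5.9 were not called in the last one (adjusted p = 0.059 to 0.134). In the monosomal against total difference R08F11.4, faah-3, ilys-5, ZK1193.2, cutl-28, mltn-3, nduo-2 and ctc-2 were not (0.0897 to 0.137). By deviations from the group mean, the numbers do not pair the 4 groups of these differences (with mrps-5 RNAi r = 0.26, 0.13 and 0.08 for polysomal with monosomal RNA). They pair 2 of 21 pairs of groups. Between paired groups the block ended no named call, but in differences it did. Every library correlated best with its own number in these 2, in polysomal with monosomal RNA of mrps-5 RNAi worms and in total with polysomal RNA of doxycycline livers, as a hint from the data. The block on the number ended 2 list calls, endothelial markers in mouse total RNA (adjusted p = 0.0514) and Kupffer markers in the mouse difference (0.0505). The cause was not tested for these settings or the next ones.

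A prior count of 2 gave 8 genes for monosomal against total, 15 for polysomal against monosomal and 0 in mouse polysomal RNA. Sample weights gave 7331, 1148 and 136 genes in worm total, polysomal and monosomal RNA and 15, 14 and 9 for the polysomal against total, monosomal against total and polysomal against monosomal differences. They gave 5979 for polysomal against total RNA with empty vector and 9 in mouse polysomal RNA, with overlaps of 1001 and 69. The estimate of the worm weights stopped before it converged and gave mrps-5 RNAi total replicate 3 a weight of 66 against 0.106 to 7.73 for the other worm libraries. Whether the count of 7331 in total RNA leans on that library was not tested. Without the monosomal libraries the counts were 992 in total RNA, 1659 in polysomal RNA and 4866 between these fractions with empty vector.

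With 1 library left out, the genes called ran from 108 to 376 in worm total RNA, 183 to 282 in polysomal RNA and 1404 to 2418 in monosomal RNA. They ran from 0 to 0 for the polysomal against total difference, 10 to 429 for monosomal against total and 29 to 511 for polysomal against monosomal. With empty vector they ran from 1420 to 1835 for polysomal against total and 3536 to 4635 for polysomal against monosomal RNA. In mouse they ran from 0 to 0 in total RNA, 33 to 68 in polysomal RNA, 0 to 10 for their difference and 4830 to 5684 between fractions with amoxicillin. The overlaps ran from 97 to 233 and 142 to 316 in worm and from 0 to 0 in mouse, and the change of mrps-5 in total RNA from 1.40 to 2.33. The lists called ran from 13 to 15, 8 to 11 and 11 to 17 in worm total, polysomal and monosomal RNA. For the 3 differences, in the order above, they ran from 9 to 14, 4 to 13 and 9 to 16, and between fractions with empty vector from 15 to 16 and 17 to 19. In mouse they ran from 8 to 17 in total RNA, 10 to 14 in polysomal RNA, 2 to 13 for the difference and 8 to 12 between fractions.

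With 200 simulated changes false calls were 0% in worm total RNA, 3.1% in polysomal RNA and 73.9% in monosomal RNA. They were 0.8%, 27.6% and 38.8% for the 3 differences and 0% and 33.6% between fractions with empty vector. In mouse they were 1.2% in total RNA, 13.6% in polysomal RNA, 3.9% for the difference and 9.9% between fractions. Simulated shares exceeded 0.05 for worm comparisons with a monosomal group, mouse polysomal RNA and the mouse fractions. Real shares depend on how many genes change and were not tested.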

Other observations

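Chosen only after the results were seen were the tests on the mitochondrial rRNAs, on the scaling of the worm lists, on hepatocyte proteins and on splits of the libraries.

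In mrps-5 RNAi worms the small subunit rRNA MTCE.7 and the mRNAs of mitochondrial DNA moved apart. Library scaling, or a few genes taking most of the reads, leaves the ratio of MTCE.7 to the large subunit rRNA MTCE.33 within a library untouched, but the log2 ratio differed by -1.53 (SE 0.11) in total RNA. The log2 ratio of MTCE.7 to the mean of 12 mRNAs differed by -2.33 (SE 0.16). This ratio is the pattern itself and argues against a changed amount of mitochondria or mtDNA only as the sole cause. A loss of small subunit rRNA where a protein of that subunit is lowered stays open. The ratio of MTCE.7 to MTCE.33 was lower in every fraction (difference -1.26, SE 0.25, in polysomal and -1.92, SE 0.22, in monosomal RNA). This was known before the test was chosen, and no protein was measured. Under the RNAi label mrps-5 RNA was higher in total and monosomal RNA. A depletion of rRNA that differs between groups and exchanged labels stay open and untested, and the ratios replaced a first test on limma's adjusted p of MTCE.7 (0.425 in total and 0.061 in polysomal RNA) that had not been met.

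In total RNA of mrps-5 RNAi worms the vitellogenin list kept its call with an estimated correlation (adjusted p = 0.0344), while the collagen and sperm lists lost theirs (0.0627 and 0.277, with 0 of 69 sperm genes called). Library scaling moves all lists alike, whereas over 3 scalings the medians of vitellogenins and collagens were at least 4.27 apart. Libraries taken at different points of development stay open: over 205 genes of these lists, deviations of total RNA libraries from their group mean correlated across genes with the polysomal effect at r = 0.40, -0.48 and 0.35 with empty vector and at -0.14, 0.21 and -0.26 with mrps-5 RNAi. The largest size was thus 0.48 in the first group and 0.26 in the second, where at least 0.3 in both had been set as the sign of such a spread, and genes are not independent replicates. Point of development and treatment cannot be told apart here, because the labels give the same stage for all worms and no other measure of their age, and a slower or faster development as an effect of mrps-5 RNAi is an untested hypothesis.

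Cholesterol synthesis transcripts were higher in doxycycline liver at the preset correlation. One library as the source is argued against by the medians with 1 of the 6 total RNA libraries left out, which ran from 0.40 to 0.66 (highest adjusted p = 1.07e-14). A lower share of other cell types in the doxycycline livers, which itself stays open, would raise all hepatocyte transcripts alike, but the secreted hepatocyte proteins had a median of 0.01 (SD 0.11). An effect of the antibiotics on cholesterol synthesis may be involved, and stays a hypothesis: with an estimated correlation the call was lost (adjusted p = 0.211 in total and 0.322 in polysomal RNA). Without untreated livers a rise with doxycycline cannot be separated from a fall with amoxicillin.

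In mouse total RNA, at the preset correlation, Kupffer cell (median -0.50), red blood cell (-0.83) and endothelial markers (-0.12) were called lower with doxycycline, and stellate cell markers were not called (0.12, adjusted p = 0.468). With an estimated correlation the 3 calls were lost (adjusted p = 0.244, 0.211 and 0.611). The endothelial call also ended without amoxicillin total replicate 3 (median -0.06, adjusted p = 0.653) or doxycycline total replicate 2 (adjusted p = 0.473), and its median was -0.21 without amoxicillin total replicate 1. The Kupffer median was -0.26 without amoxicillin total replicate 2 (adjusted p = 8.36e-05).

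The 6 libraries of a comparison of 2 groups form 10 splits, the real one included, which is too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits for worm total RNA (284, highest other 0), polysomal RNA (352, highest other 1) and monosomal RNA (1681, highest other 419). It was 1 of 10 as well for polysomal against total (2263, highest other 0) and against monosomal RNA with empty vector (4418, highest other 5) and for polysomal against total RNA with amoxicillin (5856, highest other 2). In mouse polysomal RNA it was 4 of 10 (23, highest other 34). In mouse total RNA the 10 of 10 says nothing, since the real count is 0 (highest other 0). As many lists were called in 8 of 10 splits for worm total RNA (14, highest other 17), 7 of 10 for polysomal RNA (8, highest other 11) and 1 of 10 for monosomal RNA (15, highest other 14). With empty vector it was 5 of 10 for polysomal against total (16, highest other 17) and 4 of 10 against monosomal RNA (18, highest other 19). In mouse it was 2 of 10 in total RNA (15, highest other 15), 2 of 10 in polysomal RNA (12, highest other 12) and 9 of 10 between fractions (9, highest other 17).

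For the differences between fractions 100 splits were drawn. As many genes were called in 26 for monosomal against total (49, highest other 355) and 26 for polysomal against monosomal (50, highest other 496), so chance is not excluded for these counts. Where the real count is 0 every split gives as many, so the 100 of 100 for the worm polysomal against total (highest other 899) and the mouse difference (highest other 8) say nothing about chance. As many lists were called in 52 (11, highest other 18), 64 (10, highest other 17), 9 (15, highest other 17) and 39 of 100 (11, highest other 16), for worm polysomal against total, monosomal against total, polysomal against monosomal and the mouse difference, so chance is not excluded for them either. These splits mix the treatments, and whether treatment effects enter the counts was not tested.

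A pair of mrps-5 RNAi worm libraries stood apart, as seen after the values were known. In total RNA the median log2 CPM of sperm genes was 2.19, -1.72 and 1.72 in mrps-5 RNAi replicates 1, 2 and 3 and 2.67, 3.38 and 2.71 with empty vector. In monosomal RNA it was -6.34 in mrps-5 RNAi replicate 2, the value of a gene with 0 reads there, and 2.32 and 1.38 in the others. Vitellogenins in total RNA were at 9.53, 6.44 and 8.86 with mrps-5 RNAi, and collagens at 4.32, 6.35 and 5.61.

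Further values, chosen after they were seen, belong to single mouse libraries. Reads of muscle protein genes appeared in amoxicillin total replicate 1, amoxicillin total replicate 3 and amoxicillin polysomal replicate 3. In that order there were 766, 59 and 5903 reads of Acta1, 617, 66 and 2663 of Ckm, 391, 19 and 3446 of Mb, 1651, 109 and 2544 of Myh1 and 10515, 770 and 1862 of Ttn. Gm28437 had 14402 reads in amoxicillin total replicate 2. The mitochondrial mRNA mt-Co2 had 184 reads in amoxicillin polysomal replicate 3 and 1535 and 1683 in the other libraries of that group.

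The 10 most abundant genes took 31.8% to 66.7% of the reads of a worm monosomal library, and the most abundant one up to 29.3%.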
